A study of Mus musculus with 12 samples.

How the data were processed

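Bulk pylorus RNA of wild-type and CEA424-SV40 T Ag transgenic C57BL/6 mice at 60 and 80 days of age was measured in 12 RNA-seq libraries, 3 per group. Per the labels, RNA was extracted with a Qiagen kit and libraries were made with an Illumina stranded mRNA kit. The authors deposited a table of raw counts per gene for 23420 mouse gene symbols, with no normalization. The submitters' notes name STAR 2.5.3a, HTSeq 0.9.1, edgeR 3.16.5 and the genome build mm10, without saying what each did. The gene annotation and the strand setting of the counting are not given in the sources used here. The authors also deposited a normalized signal table of 15465 genes, checked here to hold each raw count divided by 1 factor per library. The values are CPM, counts scaled to a total of 1e+06, divided further by a composition factor of 0.805 to 1.30 per library. These factors were close to the scaling factors computed below. The table's sums per library therefore ran from 768405 to 1.24e+06. Counts recovered from that table were whole for 99.997% of values, at a tolerance of 0.01 of a count, and equal to the raw counts for 100% of values in the 15442 genes matched by name. The other 23 entries had gene names turned into dates. All results below come from the raw counts unless another source is named.

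Total counts per library ranged from 20121600 to 27633715. A group with 3 counts or fewer in all was treated as at the floor, and 3 counts correspond to 0.149 CPM in the smallest library and 0.109 CPM in the largest. Intervals and floors cover counting error only, and no molecular identifiers are named in the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the 4 groups, which left 15369 genes with 99.975% of the counts, 4513 genes having 0 counts in all libraries. Library sizes were scaled by the trimmed mean of M-values (TMM), with factors of 0.805 to 1.30, and a quasi-likelihood model with 1 coefficient per group was fitted, with 8 residual degrees of freedom and a biological coefficient of variation of 24.2%. The comparisons were transgenic against wild-type at D60 and at D80, D80 against D60 within each genotype, and the interaction of the 2. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no minimum fold change.

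Before the data were examined, 56 gene lists with 760 entries were written for epithelial, stromal, neural and immune cell types of the stomach, neighbouring tissues and pathways, and 53 had at least 3 tested members. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison. The rotation test fry was run beside them. For each list the genes past the threshold were counted over all genes and adjusted over the list alone. A list's genes are called higher or lower in the text only by the gene test. Named genes followed a rule fixed at the same time, which took the 6 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM and no overlap between groups (for the interaction, without the overlap condition), up to 4 members with the smallest p-value for each list described, and 15 genes fixed in advance. The rule named 194 genes, and 191 had coordinates, from GENCODE M21 on GRCm38. Some of the named genes are not reported here. Where a group had 0 counts, fold changes are lower bounds against 3 counts over the group, and where it had 1 to 3 counts they are ratios with 95% Clopper-Pearson counting intervals. SV40 sequence was not analysed here.

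Replicate numbers in the titles did not pair libraries, as the residuals of the 18 same-number pairs had a mean correlation of -0.004, so the replicate number was not in the model. Libraries were checked for sex by Xist and 4 Y-linked genes and for neighbouring tissue by the marker lists. Alternatives also chosen then were other scaling factors, other filters on low counts, DESeq2, limma-voom, limma on the deposited normalized signal, robust dispersion, a minimum fold change of 1.5 (glmTreat), a replicate block, only the 2 groups compared, and leaving out each library. Alternatives chosen after seeing the data were sex as a covariate, counts recovered from the normalized table, leaving out Rn45s, and leaving out the wild-type D80 library with the most duodenal and the transgenic D80 library with the most pancreatic transcripts. The pipeline was tested on simulated data with planted changes in libraries of these sizes and with this spread, where it called 44.9% of 2-fold and 85.7% of 4-fold changes at D60, 52.0% and 77.6% at D80, 51.0% and 78.6% between ages in transgenic mice, 43.4% and 82.7% in wild-type mice, and 16.0% and 56.1% for the interaction, with 3 to 11 unchanged genes called. In the simulated data 98 to 100 tested genes changed per fold size, and genes varied independently of each other. The real comparisons passed up to 6354 genes, and real libraries share differences of sex and neighbouring tissue, so these rates may not carry over. The marker lists are not exclusive to 1 cell type.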

Results

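RNA was sequenced from bulk pylorus, the outlet of the stomach, of C57BL/6 wild-type mice and of CEA424-SV40 T Ag transgenic mice. In this gastric cancer model a carcinoembryonic antigen promoter drives the large T antigen of simian virus 40, an oncoprotein that binds p53 and the retinoblastoma family. Each genotype was sampled at 60 days (D60) and 80 days (D80) of age, with 3 libraries in each of the 4 groups, 12 in all. The D60 wild-type libraries held 20121600, 21841893 and 23021084 counts, and the D80 wild-type libraries 24156508, 24461130 and 27027376. The D60 transgenic libraries held 26528906, 23356363 and 24872854 counts, and the D80 transgenic libraries 27633715, 22039466 and 24833454. The labels give no treatment, and they do not say that the libraries came from separate animals, so every p-value below measures the spread between libraries only. Values are CPM, counts scaled to a total of 1e+06 and by the trimmed mean of M-values, as mean ± SD with n = 3, and fold changes are on the log2 scale with their standard error (SE).

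Most of the difference between libraries followed genotype and age. The first principal component held 62.5% of the variance, and the 3 D80 transgenic libraries sat at 94.3 to 119 on it, the D60 transgenic libraries at -13.4 to 10.5, and the 6 wild-type libraries at -82.8 to -30.1. Sex transcripts did not match across groups. Xist, the RNA that silences the inactive X chromosome, had at most 1 count in the 3 D60 wild-type libraries, which held 82.8 to 95.2 CPM of 4 Y-linked genes (counts over the library total, without the TMM factor). The 3 D80 wild-type and the 3 D60 transgenic libraries held Xist and 0 counts of the Y-linked genes. Among the D80 transgenic libraries, replicate 1 held 86.9 CPM of the Y-linked genes, on the same unscaled basis, and 0 counts of Xist, and the other 2 held Xist. At D60, genotype and sex therefore coincided in all 6 libraries. Markers of neighbouring tissue also differed. D80 wild-type replicate 3 held 13879 summed CPM of duodenal enterocyte genes, against 809.7 and 3541 in the other 2 libraries of its group, and 96.8 summed CPM of CD8 and cytotoxic lymphocyte genes, against 2.19 and 16.7. The mean over the pancreatic acinar list was higher in all 3 D80 transgenic libraries, at 5.97 to 8.11 log2 CPM, than in the 6 wild-type libraries, of which 5 were at 0.41 to 0.66 and D80 wild-type replicate 3 at 5.05. D60 transgenic replicates 1, 2 and 3 were at 4.17, 2.82 and 0.53. In summed CPM, D80 transgenic replicate 1 held 5923, against 2251 and 1804 in the other 2 libraries of its group and 2138 in D80 wild-type replicate 3. The summed level at D60 was 675 ± 177 in transgenic and 586 ± 59.4 in wild-type libraries. Hepatocyte genes were at a mean of 4.33 ± 0.42 log2 CPM in D80 transgenic and 2.79 ± 1.07 in D80 wild-type libraries.

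**Figure D1:**
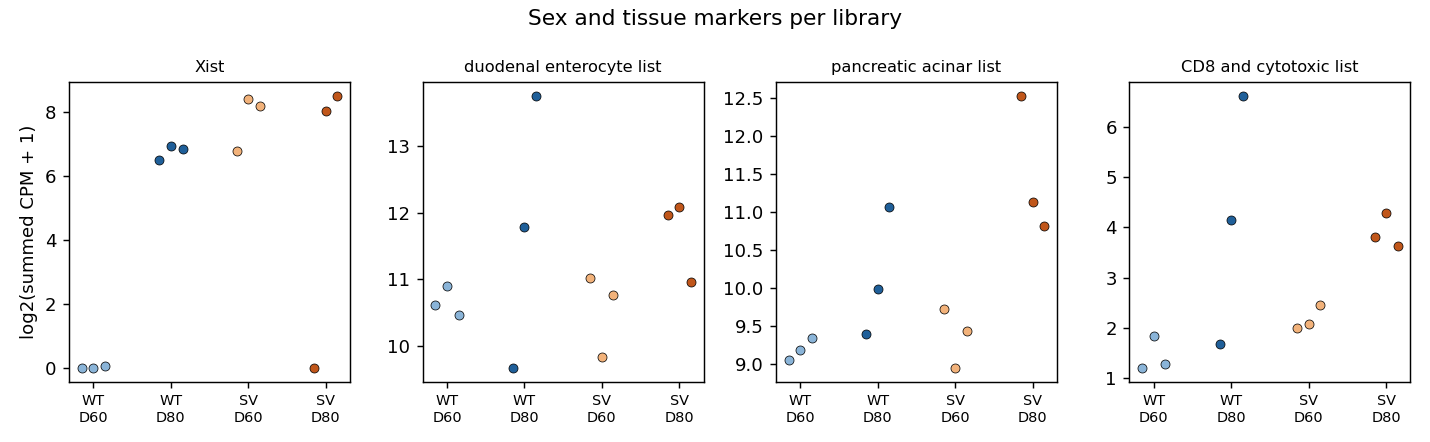
Each point is 1 library, and the vertical axes give log2 of summed CPM plus 1 for Xist and for 3 gene lists in the 4 groups (WT wild-type, SV transgenic). Xist was absent or nearly so in the 3 D60 wild-type libraries and in D80 transgenic replicate 1, and D80 wild-type replicate 3 had the highest duodenal enterocyte level, 13879 CPM, and the highest CD8 and cytotoxic level, 96.8 CPM.

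The comparison at D60 shows what distinguishes the transgenic pylorus at the younger age. Most genes of the neuroendocrine and interferon-induced lists were higher in transgenic than in wild-type mice. Chromogranin A (Chga, chromosome 12, 102554969 to 102565028 in GRCm38) rose from 70.4 ± 17.2 to 1015 ± 151 CPM, and the antiviral sensor Oas2 (chromosome 5, 120730333 to 120749853) rose from 2.20 ± 0.309 to 158 ± 3.53 CPM. Surface mucous, CD8 lymphocyte and smooth muscle genes did not pass the test. With the edgeR quasi-likelihood test, 599 of 15369 genes passed an adjusted p of 0.05, 562 higher and 37 lower in transgenic mice.

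Of the 26 tested members of the neuroendocrine programme, 20 were higher and none lower (21 higher adjusted over the list alone), with a median log2 fold change of 2.17 (camera adjusted p = 1.8e-70, and adjusted p = 0.014 with an estimated correlation). Chga (log2 fold change 3.85, SE 0.24, adjusted p = 8.6e-06) and chromogranin B (Chgb, log2 fold change 3.95, SE 0.30, adjusted p = 1.8e-05) are granule proteins of neuroendocrine cells. Of 10 gastric hormone genes, 3 were higher (3 higher and 2 lower adjusted over the list alone). They were Tph1, the serotonin-synthesis enzyme (log2 fold change 4.66, SE 0.32, adjusted p = 1.5e-05), the glucagon precursor Gcg (log2 fold change 6.70, SE 0.50, adjusted p = 1.8e-05) and secretin, Sct (log2 fold change 5.46, SE 0.96, adjusted p = 0.0061). The camera adjusted p of this list was 1.7e-05, and adjusted p = 0.21 with an estimated correlation. Gastrin (Gast, chromosome 11, 100334407 to 100336996) was at 733 ± 318 CPM in wild-type and 327 ± 86.4 in transgenic mice, adjusted p = 0.11, and passed the test with DESeq2 (adjusted p = 0.012) and without D80 wild-type replicate 1 (adjusted p = 0.029).

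The 6 transcripts with the largest increases under the naming rule included genes with next to no wild-type signal. Calcr, the calcitonin receptor, and B3gat1, a glucuronyltransferase that makes the HNK-1 epitope, had 0 counts in the 3 wild-type libraries and were at least 216-fold and at least 107-fold higher, with the floor at 3 counts over the group. Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes the tumour suppressors Ink4a and Arf, was 114-fold (95% counting interval 38.8 to 555) higher, and Rfx4, a transcription factor, 224-fold (95% counting interval 39.8 to 8869.8) higher. Dlk1, a noncanonical Notch ligand, rose by 7.20 (SE 0.58), adjusted p = 2.8e-05. Of the 14 genes of the cell-cycle inhibitor and retinoblastoma pathway list, Cdkn2a alone passed the test (3 higher adjusted over the list alone). Cdkn2c also passed with DESeq2 (adjusted p = 0.019) and with only the 2 groups compared (adjusted p = 0.021). It passed as well without D80 wild-type replicate 1 (adjusted p = 0.027) or 3 (adjusted p = 0.039) or D80 transgenic replicate 2 (adjusted p = 0.043). The proliferation marker Mki67 was at 129 ± 15.2 CPM in wild-type and 148 ± 16.5 in transgenic mice, adjusted p = 0.73. Of 26 G1/S and replication genes, 3 were higher (4 adjusted over the list alone), and 0 were without D60 wild-type replicate 3 or without D60 transgenic replicate 2, 1 without D60 wild-type replicate 1 and 6 without D80 wild-type replicate 3. The list had camera adjusted p = 1.1e-04, and adjusted p = 0.60 with an estimated correlation. The transcripts with the largest decreases included Fam25c, at -2.15 (SE 0.38), adjusted p = 0.0058, and the calcium-binding protein Casq2 of muscle, at -1.22 (SE 0.22), adjusted p = 0.0061.

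Interferon-induced genes were higher in 21 of 24 cases (23 adjusted over the list alone), with a median of 2.56 (camera adjusted p = 5.2e-68, and adjusted p = 0.014 with an estimated correlation). Oas2 (log2 fold change 6.16, SE 0.24, adjusted p = 2.1e-07), Oas1a (log2 fold change 2.68, SE 0.24, adjusted p = 4.5e-05) and Usp18, which removes the ubiquitin-like ISG15 (log2 fold change 4.21, SE 0.40, adjusted p = 8.4e-05), were among them. Of 14 genes of MHC class I antigen presentation, 9 were higher (12 adjusted over the list alone, camera adjusted p = 1.8e-11, and adjusted p = 0.14 with an estimated correlation). Nlrc5, the transactivator of these genes, rose by 3.63 (SE 0.42), and the peptide transporter Tap1 by 2.16 (SE 0.26), adjusted p = 4.1e-04. The count of 9 fell to 2 without D60 wild-type replicate 2 or 3, to 3 without D60 transgenic replicate 3 and to 4 without D60 wild-type replicate 1 or D60 transgenic replicate 2. Macrophage genes had a median of 1.22, with 2 of 15 higher (11 adjusted over the list alone, camera adjusted p = 1.9e-06, and adjusted p = 0.55 with an estimated correlation). This count was 0 without D60 wild-type replicate 1 or 3, D60 transgenic replicate 2 or 3, D80 wild-type replicate 2 or D80 transgenic replicate 2 or 3. It was 1 without D80 transgenic replicate 1, 5 without D60 transgenic replicate 1 and 6 without D60 wild-type replicate 2. None of 9 CD8 and cytotoxic genes passed, and Cd8a (chromosome 6, 71373427 to 71379173) was at 0.147 ± 0.119 and 0.237 ± 0.0916 CPM. Of 15 smooth muscle genes, 0 passed over all genes and 9 were lower adjusted over the list alone, with 2 lower over all genes without D80 wild-type replicate 1 and 6 with DESeq2. The smooth muscle median was -0.66 (camera adjusted p = 1.0e-07, and adjusted p = 0.55 with an estimated correlation). None of 11 surface mucous genes passed, and Muc5ac was at 8099 ± 3378 and 5068 ± 587 CPM.

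Genotype could not be separated from sex at D60 by design. Only the D80 transgenic libraries, 1 male-type and 2 female-type, identify an effect of sex used as a covariate. That effect is the deviation of replicate 1, which also held the most pancreatic acinar transcripts, so it cannot be told apart from other traits of this library. At D80 such a fit acts like leaving that library out. With sex as a covariate, 85 genes passed at D60, with 11 neuroendocrine, 5 interferon-induced and 0 MHC class I genes among them. The list medians were then 1.69 in place of 2.17, 2.30 in place of 2.56 and 0.73 in place of 0.86, while the median SE of their genes grew from 0.29 to 0.46, from 0.35 to 0.62 and from 0.23 to 0.42. The calls of Sct (4.70, SE 1.45), Nlrc5 (3.10, SE 0.66) and Tap1 (1.92, SE 0.45) ended with a larger SE and a log2 fold change close to that without the covariate. Those of Fam25c (-1.35, SE 0.75) and Casq2 (-0.64, SE 0.36) ended with a smaller change as well. The count over all genes was 378 without D60 wild-type replicate 3 and 388 without D60 transgenic replicate 2.

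**Figure D2:**
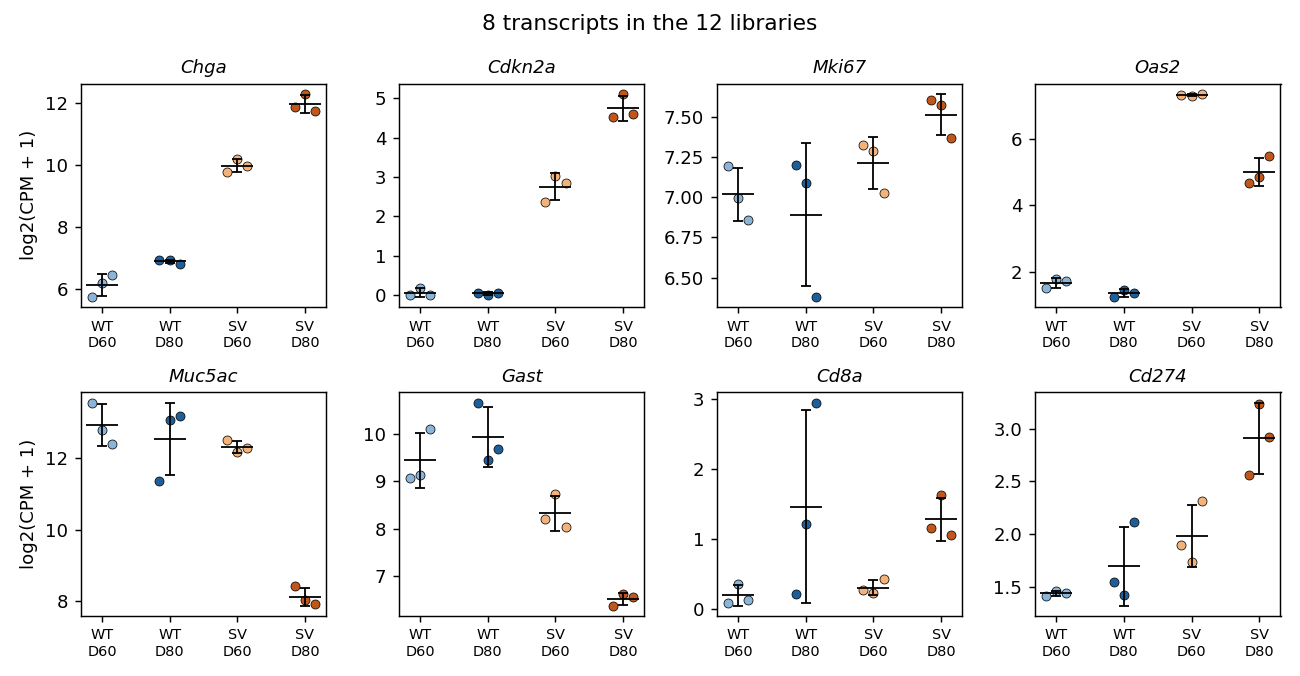
Each point is 1 library, the vertical axes give log2 of CPM plus 1 for 8 transcripts, and horizontal bars and whiskers are mean and SD of 3 libraries per group (WT wild-type, SV transgenic). Chga and Cdkn2a were higher in both transgenic groups than in either wild-type group, Oas2 was highest in D60 transgenic mice, at 158 ± 3.53 CPM, and Muc5ac was lowest in D80 transgenic mice, at 283 ± 51.1 CPM.

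At D80 the comparison asks what distinguishes the transgenic pylorus at the older age, in a series whose title concerns immune-excluded gastric cancer. Neuroendocrine transcripts were higher still, with Chga at 4109 ± 843 CPM against 117 ± 4.88 in wild-type mice. Transcripts of surface mucous cells and of smooth muscle were lower, with the mucin Muc5ac (chromosome 7, 141788972 to 141819231) at 283 ± 51.1 against 6745 ± 3585 CPM. Proliferation, neutrophil, macrophage and inflammatory cytokine genes were higher, while none of the CD8 and cytotoxic lymphocyte genes passed the test. By the edgeR quasi-likelihood test, 6354 of 15369 genes passed, 2974 higher and 3380 lower in transgenic mice. With so many genes passing, the counts of each list below are to be read against these shares of all genes.

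Of 26 neuroendocrine genes, 23 were higher and 2 lower (the same counts adjusted over the list alone), with a median of 4.03 (camera adjusted p = 8.6e-48, and adjusted p = 0.092 with an estimated correlation). Pcsk1, a prohormone convertase (log2 fold change 4.81, SE 0.21, adjusted p = 1.5e-07), and the transcription factor Nkx2-2 (log2 fold change 4.19, SE 0.22, adjusted p = 2.9e-07) were examples. The 2 lower members, picked out after their values were seen, were the transcription factor Isl1, at -1.11, and the tubulin-binding protein Stmn2, at -0.56. Both were no longer called without D80 transgenic replicate 2, with upper-quartile factors or with no composition factor, and 1 was without D80 wild-type replicate 2 or 3 or D80 transgenic replicate 1 or 3. Gastric hormone genes moved apart, 5 higher and 3 lower of 10 (the same adjusted over the list alone, camera adjusted p = 0.030, and adjusted p = 0.66 with an estimated correlation). Gcg (log2 fold change 9.67, SE 0.52, adjusted p = 2.9e-07), Tph1 (log2 fold change 6.61, SE 0.35, adjusted p = 2.9e-07) and cholecystokinin, Cck (log2 fold change 3.12, SE 0.36, adjusted p = 6.3e-05), rose. Gast fell from 1044 ± 494 to 91.2 ± 7.82 CPM, adjusted p = 3.6e-05. Calcr was at least 977-fold and B3gat1 at least 562-fold higher, with 0 wild-type counts. The opioid precursor Pdyn rose by 10.66 (SE 0.40), adjusted p = 7.4e-08. Enteric neuron genes also moved apart, 6 higher and 4 lower of 13 (the same adjusted over the list alone, camera adjusted p = 0.014, and adjusted p = 0.70 with an estimated correlation). The RNA-binding protein Elavl3 (log2 fold change 4.85, SE 0.45, adjusted p = 1.2e-05) and the clathrin adaptor Snap91 (log2 fold change 4.39, SE 0.35, adjusted p = 4.0e-06) were higher. Lower members picked out after their values were seen were Nos1 at -2.26, Prph at -1.43 and Hand2 at -1.05.

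Most surface mucous genes and all smooth muscle genes were lower. Of 11 surface mucous (pit) cell genes, 9 were lower and none higher (10 lower adjusted over the list alone), with a median of -2.15 (camera adjusted p = 5.2e-06, and adjusted p = 0.66 with an estimated correlation). Muc5ac changed by -4.58 (SE 0.49), adjusted p = 3.5e-05, and the membrane protein Vsig1 by -2.02 (SE 0.24). Of 10 gland mucous cell genes, 1 was lower (the same adjusted over the list alone), the pepsinogen Pgc (log2 fold change -2.64, SE 0.39, adjusted p = 4.0e-04). In that list 4 were lower without D80 wild-type replicate 3, and without D80 wild-type replicate 1 the list's median was 0.08 in place of -0.52. All 15 smooth muscle genes were lower (all adjusted over the list alone), with a median of -2.20 (camera adjusted p = 7.1e-15, and adjusted p = 0.66 with an estimated correlation). Desmin (Des) fell from 2460.4 ± 705 to 324 ± 28.7 CPM and gamma-2 actin (Actg2) from 1699 ± 401 to 239 ± 8.87 CPM. Parietal cell genes moved apart, 4 higher and 2 lower of 11 (the same adjusted over the list alone, camera adjusted p = 0.024, and adjusted p = 0.60 with an estimated correlation). Hdc, the histamine-synthesis enzyme (log2 fold change 7.16, SE 0.25, adjusted p = 7.1e-08), and the proton pump subunit Atp4a, at 8.47 ± 3.81 CPM (log2 fold change 4.0, SE 0.52, adjusted p = 1.3e-04), were higher. Enterochromaffin-like cells express Hdc, so its rise is not specific to parietal cells. The 2 lower parietal members were 1 with upper-quartile factors, with no composition factor, and in the fits without D60 wild-type replicate 1 or 3, D60 transgenic replicate 3, D80 wild-type replicate 1 or any of the 3 D80 transgenic libraries.

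Most cell-cycle genes rose. Of 26 G1/S and replication genes, 22 were higher (the same adjusted over the list alone), with a median of 0.85 (camera adjusted p = 3.0e-06, and adjusted p = 0.66 with an estimated correlation). Of 26 G2/M and mitosis genes, 21 were higher (24 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 2.8e-05, and adjusted p = 0.71 with an estimated correlation). The cyclin Ccne2 (log2 fold change 1.87, SE 0.20, adjusted p = 3.8e-05) and the kinetochore protein Cenpf (log2 fold change 1.49, SE 0.23, adjusted p = 4.3e-04) were examples. Mki67 was at 183 ± 16.1 against 121 ± 34.2 CPM (log2 fold change 0.59, SE 0.19, adjusted p = 0.029). The call ended without D80 wild-type replicate 3 (log2 fold change 0.37, adjusted p = 0.065) and without D80 transgenic replicate 1 (adjusted p = 0.077) or 2 (adjusted p = 0.080). It also ended with sex as a covariate (0.54, SE 0.22, adjusted p = 0.077), a fit that at D80 acts like leaving out D80 transgenic replicate 1. The Mki67 call ended as well with only the 2 groups compared (adjusted p = 0.068) and without the 2 libraries with the most duodenal or pancreatic transcripts (adjusted p = 0.15). DNA damage response genes were higher in 12 of 16 cases (13 adjusted over the list alone, camera adjusted p = 9.9e-04, and adjusted p = 0.70 with an estimated correlation), Brca1 among them (log2 fold change 1.32, SE 0.22, adjusted p = 8.3e-04). In that list 1 member was lower without D80 wild-type replicate 3. Cdkn2a was 909.8-fold (95% counting interval 252 to 7516) higher. Among the 14 genes of its list 4 were higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.20, and adjusted p = 0.66 with an estimated correlation), with Cdkn2d (log2 fold change 1.68, SE 0.19, adjusted p = 4.6e-05) and Cdkn2c (log2 fold change 1.45, SE 0.18, adjusted p = 9.1e-05) higher. With no composition factor 6 were higher and 1 lower. The p53 target list had 5 higher and 5 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.89, and adjusted p = 0.88 with an estimated correlation). In that list 3 were lower when D80 wild-type replicate 2 or 3 or D80 transgenic replicate 2 or 3 was left out, and 10 were higher and 0 lower with no composition factor. Trp53 itself was at 44.8 ± 4.63 against 39.1 ± 7.47 CPM, adjusted p = 0.35.

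Myeloid and inflammatory transcripts rose. All 14 tested inflammatory cytokines and neutrophil chemokines were higher (all adjusted over the list alone), with a median of 4.58 (camera adjusted p = 3.0e-06, and adjusted p = 0.66 with an estimated correlation). Among them were Il11 (log2 fold change 5.96, SE 0.69, adjusted p = 5.8e-05) and Il1b, at 45.4 ± 31.7 against 1.14 ± 0.162 CPM. All 9 tested neutrophil genes were higher (all adjusted over the list alone), with a median of 5.0 (camera adjusted p = 2.6e-04, and adjusted p = 0.66 with an estimated correlation). Examples were the granulocyte colony-stimulating factor receptor Csf3r (log2 fold change 5.0, SE 0.76, adjusted p = 4.6e-04) and Retnlg (log2 fold change 3.70, SE 0.37, adjusted p = 1.9e-05). The tested genes were 14 of 16 and 9 of 11 in the count table. In each of these 2 lists, 2 tested genes were at 1 CPM or more in wild-type mice. The filter keeps a gene that is high in 1 group alone, so genes this low in wild-type mice could hardly be called lower. Macrophage genes were higher in 12 of 15 cases (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0068, and adjusted p = 0.71 with an estimated correlation), with the Fc receptor Fcgr1 at 2.58 (SE 0.43). In that list 1 member was also lower over all genes without D60 wild-type replicate 3, D60 transgenic replicate 1 or 3 or D80 wild-type replicate 1. B-cell genes were higher in 9 of 11 cases (10 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.73 with an estimated correlation), at 38.0 ± 36.5 against 9.92 ± 3.2 summed CPM. This was 5 genes without D80 wild-type replicate 2 or without D80 transgenic replicate 3, which alone held 80.2 CPM. Of the 11 tested B-cell genes, 1 was at 1 CPM or more in wild-type mice, so the same limit holds.

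T-cell transcripts were scarce. None of 9 CD8 and cytotoxic lymphocyte genes passed the test (camera adjusted p = 1.0, and adjusted p = 1.0 with an estimated correlation), and their median was -0.90. Their summed level was 14.3 ± 3.66 CPM in D80 transgenic and 38.6 ± 51.0 in D80 wild-type libraries. It was 3.55 ± 0.81 CPM in D60 transgenic and 1.77 ± 0.71 in D60 wild-type libraries, so it was higher at D80 than at D60 in transgenic mice as well. Cd8a was at 1.47 ± 0.550 CPM in transgenic and 2.75 ± 3.52 in wild-type mice, adjusted p = 0.42. Without D80 wild-type replicate 3, the library with the most duodenal and cytotoxic transcripts, 2 of the 9 were higher and the median was 0.80. Without D80 wild-type replicate 1, 4 were lower, and 1 was higher with limma-voom or with no composition factor. Of 13 pan T-cell genes 2 were higher (1 adjusted over the list alone, camera adjusted p = 0.12, and adjusted p = 0.76 with an estimated correlation). They were Thy1, which neurons and fibroblasts also express (log2 fold change 3.68, SE 0.33, adjusted p = 8.2e-06), and Cd2 (log2 fold change 2.17, SE 0.68, adjusted p = 0.024). The Cd2 call ended without D80 wild-type replicate 2 (adjusted p = 0.086) or D80 transgenic replicate 3 (adjusted p = 0.11), and 6 pan T-cell genes were higher without D80 wild-type replicate 3. Cd3e, a subunit of the T-cell receptor complex, was at 1.77 ± 0.279 and 2.14 ± 2.19 CPM, adjusted p = 0.78. Of 8 regulatory T-cell genes 5 were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.074, and adjusted p = 0.66 with an estimated correlation). The transcription factor Foxp3 was at 1.65 ± 0.232 against 0.0730 ± 0.0672 CPM (log2 fold change 4.43, SE 0.80, adjusted p = 0.0013). The lower member was not called with upper-quartile factors, with no composition factor, or without D80 wild-type replicate 2 or any of the 3 D80 transgenic libraries. Of 18 inhibitory and costimulatory checkpoints, 10 were higher (12 adjusted over the list alone, camera adjusted p = 0.010, and adjusted p = 0.66 with an estimated correlation), 6 without D80 transgenic replicate 3, and 2 were lower without D80 wild-type replicate 1. Pdcd1, which encodes the receptor PD-1, had 0 wild-type counts at D80 and was at least 32.1-fold higher, and its ligand Cd274 rose from 2.31 ± 0.899 to 6.65 ± 1.77 CPM (log2 fold change 1.52, SE 0.31, adjusted p = 0.0029). Interferon-induced genes were higher in 16 of 24 cases (17 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 8.0e-05, and adjusted p = 0.70 with an estimated correlation), Oas2 among them (log2 fold change 4.33, SE 0.23, adjusted p = 2.9e-07). Of these genes 1 was lower without D80 wild-type replicate 1. T-cell-recruiting chemokines were higher in 6 of 9 cases (7 adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.70 with an estimated correlation), Cxcl12 among them (log2 fold change 2.01, SE 0.29, adjusted p = 3.1e-04).

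Of 14 activated fibroblast genes, 8 were higher (the same adjusted over the list alone, camera adjusted p = 0.015, and adjusted p = 0.70 with an estimated correlation), with the collagenase Mmp13 at 4.14 (SE 0.51) and the BMP antagonist Grem1 at 1.55 (SE 0.29). Of 14 TGF-beta pathway genes and targets, 5 were higher (the same adjusted over the list alone, camera adjusted p = 0.072, and adjusted p = 0.70 with an estimated correlation). Tgfb1 was at 58.3 ± 11.8 against 20.2 ± 5.02 CPM (log2 fold change 1.53, SE 0.27, adjusted p = 0.0012), and 2 genes of the list were lower without D80 wild-type replicate 1. With no composition factor 10 of the 14 were higher, with a median of 0.98 in place of 0.55. Endothelial genes were higher in 11 of 16 cases (12 adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.75 with an estimated correlation), such as endoglin, Eng (log2 fold change 1.13, SE 0.24, adjusted p = 0.0032). This count was 5 without D80 wild-type replicate 2 or 3 or D80 transgenic replicate 3, and 6 without D80 transgenic replicate 2. The angiogenic factor Vegfa rose from 47.6 ± 12.1 to 75.8 ± 8.49 CPM (log2 fold change 0.67, SE 0.19, adjusted p = 0.014), a call that ended without D80 wild-type replicate 2 (adjusted p = 0.057) or D80 transgenic replicate 2 (adjusted p = 0.056). Hypoxia and glycolysis genes were lower in 6 of 14 cases (the same adjusted over the list alone, camera adjusted p = 0.067, and adjusted p = 0.73 with an estimated correlation), such as the kinase Pdk1 (log2 fold change -0.70, SE 0.14, adjusted p = 0.0028). This count, with Pdk1 in it, was 0 with no composition factor, 1 without D80 transgenic replicate 3, 3 without D80 wild-type replicate 2 or 3 or D80 transgenic replicate 1, and 12 without D80 wild-type replicate 1.

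At D80 the balance of higher and lower genes rests on the scaling, with 3571 higher and 2093 lower with upper-quartile factors and 5104 higher and 1001 lower with no composition factor. These settings moved the median log2 fold change of all genes from -0.07 to 0.08 and 0.34. Of 14 pancreatic acinar genes 5 were higher (10 adjusted over the list alone), with a median of 3.85 (camera adjusted p = 0.060, and adjusted p = 0.76 with an estimated correlation). That count was 0 without D80 wild-type replicate 2 or D80 transgenic replicate 1 or with sex as a covariate, 9 with no composition factor and 12 without D80 wild-type replicate 3. The camera calls at D80 were lost with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, called 31 of 53 lists.

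**Figure D3:**
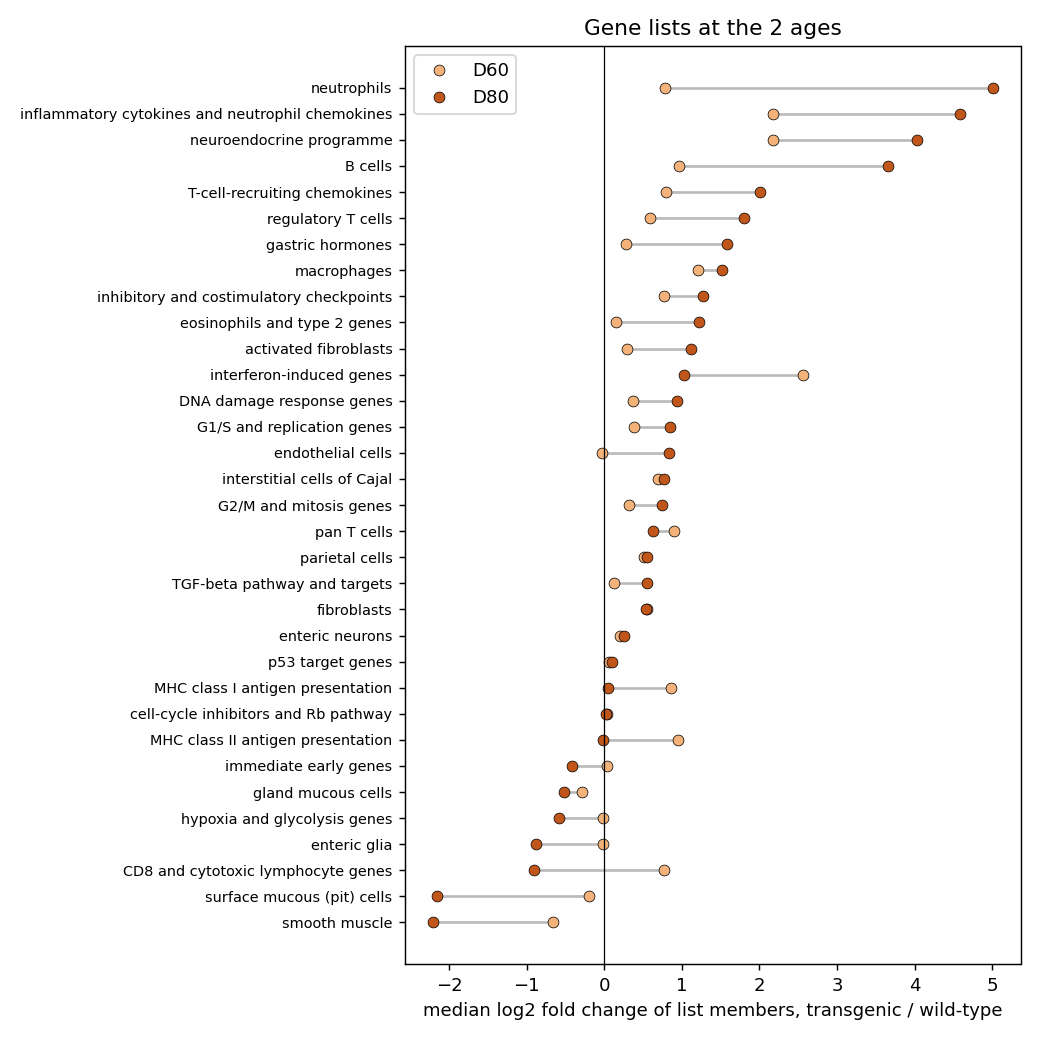
Each row is a gene list, the horizontal axis gives the median log2 fold change of its tested members, transgenic over wild-type, and the 2 points are D60 and D80. The neuroendocrine programme moved from 2.17 to 4.03, interferon-induced genes from 2.56 to 1.03 and smooth muscle from -0.66 to -2.20.

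The genotype differences at the 2 ages overlapped. Of the 562 genes higher at D60, 502 were also higher at D80, against 109 for independent lists of these sizes, and of the 37 lower genes 35 were also lower, against 8.14. Across the 15369 genes, which are not independent replicates, the log2 fold changes at the 2 ages had Pearson's r = 0.680 and Spearman's rho = 0.596. The genes higher at D60 had a median log2 fold change of 2.30 at D60 and 3.67 at D80, and 422 of the 562 had the larger change at D80. The shared count of 537 was 83 with sex as a covariate, 351 without D60 wild-type replicate 3 and 349 without D60 transgenic replicate 2.

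**Figure D4:**
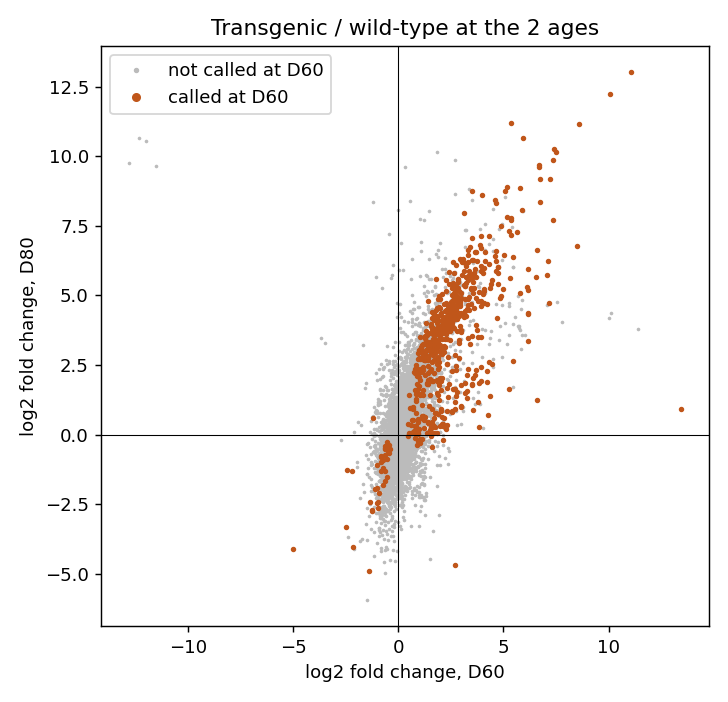
Each point is 1 tested gene, the horizontal axis gives its log2 fold change, transgenic over wild-type, at D60 and the vertical axis that at D80, with the 599 genes that passed at D60 in orange. Of these genes 587 had the same sign at D80, and the 4 Y-linked genes lie alone at the upper left.

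Within transgenic mice, the comparison of D80 with D60 follows the change with age under the transgene. Neuroendocrine, inflammatory and endothelial transcripts were higher at D80, and surface mucous, smooth muscle and interferon-induced transcripts were lower. Pcsk1 rose from 64.6 ± 7.77 to 367 ± 68.4 CPM, Muc5ac fell from 5068 ± 587 to 283 ± 51.1 CPM, and Oas2 fell from 158 ± 3.53 to 31.9 ± 10.3 CPM. The edgeR test passed 5490 genes, 2725 higher and 2765 lower at D80.

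Of 26 neuroendocrine genes 22 were higher and 2 lower (23 and 2 adjusted over the list alone), with a median of 2.09 (camera adjusted p = 5.6e-24, and adjusted p = 0.42 with an estimated correlation). The synaptic vesicle protein Syp was among the higher genes (log2 fold change 2.26, SE 0.20, adjusted p = 8.0e-05). The lower members were 0 without D60 transgenic replicate 2 or any of the 3 D80 transgenic libraries, and 1 without D60 wild-type replicate 1 or D60 transgenic replicate 1 or 3. Interferon-induced genes were lower in 17 of 24 cases and higher in 1 (19 and 1 adjusted over the list alone), with a median of -1.27 (camera adjusted p = 7.2e-08, and adjusted p = 0.54 with an estimated correlation). Oas2 (log2 fold change -2.30, SE 0.19, adjusted p = 6.9e-05) and Oas1a (log2 fold change -1.72, SE 0.23, adjusted p = 3.8e-04) were lower. The higher member was Ifit2, at 0.90, picked out after its value was seen and not called without D60 transgenic replicate 1 or 3 or D80 transgenic replicate 2. The count of lower interferon-induced genes was 9 without D80 transgenic replicate 1 or 2 or with sex as a covariate, and 11 without D60 transgenic replicate 3 or with no composition factor. Surface mucous genes were lower in 10 of 11 cases (the same adjusted over the list alone), with a median of -2.36 (camera adjusted p = 1.1e-09, and adjusted p = 0.47 with an estimated correlation). Smooth muscle genes were lower in 14 of 15 (the same adjusted over the list alone), with a median of -1.94 (camera adjusted p = 7.4e-16, and adjusted p = 0.51 with an estimated correlation). Myh11, smooth muscle myosin, changed by -2.27 (SE 0.29), adjusted p = 3.5e-04. All 14 tested inflammatory cytokines and neutrophil chemokines (camera adjusted p = 2.8e-08, and adjusted p = 0.51 with an estimated correlation) and all 9 tested neutrophil genes (camera adjusted p = 7.8e-06, and adjusted p = 0.51 with an estimated correlation) were higher, also adjusted over the list alone. The filter keeps genes that are high in 1 group alone, which limits both counts. The cytokine Osm was 99-fold (95% counting interval 33.6 to 482) and the chemokine receptor Cxcr2 144-fold (95% counting interval 48.9 to 699) higher, and the acute-phase protein Hp rose by 6.53 (SE 0.95), adjusted p = 6.5e-04. Endothelial genes were higher in 13 of 16 cases (14 adjusted over the list alone, camera adjusted p = 1.8e-05, and adjusted p = 0.60 with an estimated correlation), VE-cadherin, Cdh5, among them (log2 fold change 1.5, SE 0.24, adjusted p = 0.0011).

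Pancreatic acinar genes were higher in 9 of 14 cases (11 adjusted over the list alone, camera adjusted p = 0.016, and adjusted p = 0.60 with an estimated correlation). The count was 1 without D60 transgenic replicate 2 or 3 or D80 transgenic replicate 1, 3 without D80 transgenic replicate 3, 4 without D80 transgenic replicate 2 and 5 without D60 wild-type replicate 2 or 3. The trypsinogen Try5 was at 2.95 ± 2.91 CPM at D60 and 199 ± 193 at D80 (log2 fold change 6.07, SE 1.64, adjusted p = 0.015). The count over all genes was 3507 without D80 transgenic replicate 2, and with no composition factor it split as 5154 higher and 1098 lower, with the median of all genes at 0.39 in place of 0.02.

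In wild-type mice, the comparison of D80 with D60 measures the change with age without the transgene, and the groups also differed in sex, 3 male-type against 3 female-type libraries. No gene passed in the edgeR test, where the lowest adjusted p was 0.076 and 1925 genes had an unadjusted p under 0.05. Xist was among the genes not called, although it had at most 1 count per library at D60 and 2218 to 2768 at D80. The Y-linked genes were not called either, at 1666 to 2080 summed counts per library at D60 and 0 at D80. The test thus missed differences that are plain in the counts, so its count of 0 does not show that no gene changed. DESeq2 called 260 genes, edgeR on these 2 groups alone called 5, and limma-voom and limma on the deposited normalized table called 0. Duodenal enterocyte genes had a median of 2.44, with 10 of 18 higher adjusted over the list alone (camera adjusted p = 6.5e-08, and adjusted p = 0.46 with an estimated correlation). The aminopeptidase Anpep was at 33.9 ± 5.88 CPM at D60 and 96.7 ± 16.0 at D80 (log2 fold change 1.51, SE 0.21, adjusted p = 0.090). CD8 and cytotoxic lymphocyte genes had a median of 4.0, with 7 of 9 higher adjusted over the list alone (camera adjusted p = 1.9e-07, and adjusted p = 0.30 with an estimated correlation). The granzyme Gzma was at 0.558 ± 0.217 and 18.2 ± 25.1 CPM, adjusted p = 0.29. MHC class II antigen presentation genes had a median of 1.73, with 8 of 10 higher adjusted over the list alone (camera adjusted p = 4.0e-09, and adjusted p = 0.30 with an estimated correlation). Fibroblast genes had a median of 0.70, with 3 of 14 higher adjusted over the list alone (camera adjusted p = 5.4e-09, and adjusted p = 0.30 with an estimated correlation). Without D80 wild-type replicate 3 the median of duodenal enterocyte genes was 1.19, that of CD8 and cytotoxic genes 2.24 and that of MHC class II genes 1.03. Without D80 wild-type replicate 1, the library with the fewest duodenal transcripts, 396 genes passed, with 9 duodenal enterocyte, 7 CD8 and cytotoxic, 6 MHC class II and 1 fibroblast genes among them, Anpep (adjusted p = 0.024) and Gzma (adjusted p = 0.030) included. Without D80 transgenic replicate 1 the count was 8, and it was 1 without D60 transgenic replicate 1 or D80 transgenic replicate 3; Anpep passed without D80 transgenic replicate 1 (adjusted p = 0.032) or 3 (adjusted p = 0.027).

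The interaction tests whether the genotype difference itself changed between D60 and D80. Sex also enters it, since the wild-type libraries were 3 male-type at D60 and 3 female-type at D80. The transgenic libraries were 3 female-type at D60, and 2 female-type and 1 male-type at D80. A change of the genotype difference with age is therefore not separated from sex. Genes past the test included 18 of 26 neuroendocrine genes, with a positive value, and 10 of 15 smooth muscle, 7 of 24 interferon-induced and 4 of 11 surface mucous genes, with a negative value. The camera calls of these lists were lost with an estimated correlation. The edgeR test passed 768 genes, 425 with a positive and 343 with a negative interaction. For Scg2, secretogranin II, it was 2.93 (SE 0.42), adjusted p = 0.0072, for Muc5ac -3.90 (SE 0.62), adjusted p = 0.0096, and for Oas2 -1.82 (SE 0.30), adjusted p = 0.011.

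Of 26 neuroendocrine genes 18 had a positive interaction (21 adjusted over the list alone, camera adjusted p = 8.2e-25, and adjusted p = 0.40 with an estimated correlation), with Scg3 at 2.02 (SE 0.25) and Cpe at 1.99 (SE 0.30). The count was 10 without D60 transgenic replicate 3 and 11 without D80 transgenic replicate 2. Negative interactions were found for 10 of 15 smooth muscle genes (14 adjusted over the list alone, camera adjusted p = 1.6e-14, and adjusted p = 0.51 with an estimated correlation), such as the kinase Mylk (log2 fold change -1.92, SE 0.33, adjusted p = 0.012). That count was 2 without D60 transgenic replicate 3 or D80 transgenic replicate 2 or 3, 3 without D60 wild-type replicate 3 or with no composition factor, 5 without D60 wild-type replicate 2 or D80 wild-type replicate 3, and 6 without D60 transgenic replicate 2. For 7 of 24 interferon-induced genes the interaction was negative (19 adjusted over the list alone, camera adjusted p = 7.8e-12, and adjusted p = 0.51 with an estimated correlation). That count was 2 without D60 transgenic replicate 3 or D80 transgenic replicate 2 or with no composition factor, 3 without D80 wild-type replicate 3, 4 without D60 wild-type replicate 2, D60 transgenic replicate 1, D80 wild-type replicate 2 or D80 transgenic replicate 3, and 20 without D80 wild-type replicate 1. The same held for 4 of 11 surface mucous genes (10 adjusted over the list alone, camera adjusted p = 8.8e-11, and adjusted p = 0.45 with an estimated correlation). That count was 9 without D80 wild-type replicate 1 and 2 without D60 wild-type replicate 2 or 3, D60 transgenic replicate 3 or D80 transgenic replicate 2 or 3. Pdyn (log2 fold change 4.70, SE 0.63, adjusted p = 0.0051) and gastrin-releasing peptide, Grp (log2 fold change 3.76, SE 0.47, adjusted p = 0.0046), had large positive interactions.

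The count of 768 ranged from 193 without D60 transgenic replicate 3 to 2419 without D80 wild-type replicate 1. It was 390 without D60 wild-type replicate 2, 312 without D60 wild-type replicate 3, 458 without D80 wild-type replicate 2, 425 without D80 wild-type replicate 3, 250 without D80 transgenic replicate 2 and 343 without D80 transgenic replicate 3. The interaction calls of Muc5ac (-4.48, adjusted p = 0.099), Mylk (-2.19, adjusted p = 0.11) and Oas2 (-1.11, adjusted p = 0.22) ended with sex as a covariate, and that of Oas2 also with limma-voom (adjusted p = 0.065). With sex as a covariate 99 genes passed, including 5 neuroendocrine, 0 smooth muscle, 0 interferon-induced and 0 surface mucous genes. The list medians were then 2.37 in place of 1.83, -1.74 in place of -1.64, -1.10 in place of -1.57 and -3.06 in place of -2.01, and the median SE of their genes grew from 0.39 to 0.63, from 0.37 to 0.68, from 0.49 to 0.86 and from 0.62 to 1.13. The split was 520 positive and 136 negative with no composition factor and 477 and 252 with upper-quartile factors.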

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

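Of the tests below, those of macrophages and of interferon-induced genes among D80 females and both on smooth muscle were chosen only after the result was seen, and those of sex and the relabelling after the main comparisons but before their own values. The results named here passed the interaction test, which asks whether the genotype difference changed between D60 and D80. They are lists described in the report, and genes with the largest genotype or interaction changes under the naming rule or fixed in advance. Genes named only as members of a list, such as Scg2, Oas2 and Mylk, are not repeated here. The sex types of the groups also enter the interaction, so a changed genotype difference is not separated from sex in these results. Values are interaction log2 values, for lists the median of their members. All list calls of this kind, made by camera at a preset correlation, were lost with an estimated correlation (adjusted p from 0.40 to 0.78).

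Lists with a positive value were neutrophils (3.73), inflammatory cytokines and neutrophil chemokines (1.93), the neuroendocrine programme (1.83), B cells (1.60), activated fibroblasts (0.93), endothelial cells (0.80), DNA damage response genes (0.54), G1/S and replication genes (0.45), G2/M and mitosis genes (0.42), the TGF-beta pathway and targets (0.33) and enteric neurons (0.12). Lists with a negative value were surface mucous (pit) cells (-2.01), smooth muscle (-1.64), interferon-induced genes (-1.57), MHC class I antigen presentation (-0.84) and hypoxia and glycolysis genes (-0.56). The other 2 of the 18 lists called were the sex-linked and the erythroid and blood genes, kept as checks of the libraries. Genes of this selection with a positive interaction were Hp (6.76), Pdyn (4.70), Wisp2 (4.11), Cpxm1 (3.86), Grp (3.76), St8sia5 (3.67), Atp4a (3.03), Gcg (2.97), Kcnip2 (1.75) and Chga (1.29). Pdcd1 had a fitted value of 8.08, which is no bound, since its D80 wild-type group had 0 counts. Those of this selection with a negative interaction were Muc5ac (-3.90), Ly6g6c (-3.89), Fosb (-3.67), Mogat1 (-3.63), Apol9b (-3.62), Apol9a (-3.57), Smpx (-3.49), Ngb (-3.43), Gast (-2.35) and Casq2 (-1.52).

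The first pattern weighed is the set of transcripts higher in D60 transgenic than in D60 wild-type mice, interferon-induced genes among them, where genotype and sex coincided. Against sex as the whole cause, 85.0% of 566 autosomal D60 calls measured in both were called the same way in a comparison of D80 females alone, which shares no library with D60, against 15.6% for independent lists. Of the 21 interferon-induced genes called higher at D60, 90.5% were also higher in D60 transgenic than in D80 wild-type libraries, all female, but this reuses the D60 transgenic libraries, where 66.8% of all autosomal D60 calls repeat, and among D80 females, which share none, 7 of the 21 were higher, against 16.1% of all genes. From D60 to D80 in transgenic mice the interferon list moved by -2.42 (SE 0.33, log2) relative to the macrophage list. This argues against interferon-induced genes following macrophage genes alike at both ages. It does not decide on more macrophages as the cause at D60, since it measures a later change. An effect of the transgene and its age course may account for the pattern. A part played by macrophages, by sex, and by age in the all-female comparison stays open.

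The second pattern is the lower level of smooth muscle genes in D80 transgenic mice. Endothelial genes moved above smooth muscle genes by 2.95 (SE 0.13, log2 CPM), which argues against a dilution that lowers both lists alike. It does not decide on dilution by added tumour and immune cells, since added tissue may hold endothelial cells of its own, so dilution stays open. Less of the muscle wall in the tissue taken and a loss of muscle transcripts in the same tissue cannot be told apart, since enteric glia genes, which lie in that wall, had a median of -0.88 (quartiles -1.04 and -0.61) at D80, between the bounds set for either. In that list of 8 glia genes, all at 1 CPM or more in wild-type mice and none in another list, 3 were lower over all genes and adjusted over the list alone. The count was 5 without D60 wild-type replicate 1, 2 without D80 wild-type replicate 1 or 2, 1 without D80 wild-type replicate 3 or D80 transgenic replicate 2, and 0 without D80 transgenic replicate 3 or with no composition factor.

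Relabelling the libraries gave the following. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with the most genes at D60 (599, highest other 0), at D80 (6354, highest other 0) and between ages in transgenic mice (5490, highest other 0). Between ages in wild-type mice all 10 splits gave at least the real count of 0, and the highest other was 1. The interaction count of 768 was reached by 7 of 100 splits, the real one included, with 5979 as the highest other, so chance is not excluded by this test. All 6 others kept the D80 libraries parted by genotype, a structure of the samples, and the 85 splits that part neither age by genotype called at most 0 genes. The overlap of 537 genes was reached by 1 of 100 splits (highest other 1), but only 1 of the 99 others called genes at both ages, so this test decides nothing on the overlap. The number of lists called by camera was as large in 2 of 10 splits at D60 (23, highest other 27), 6 of 10 at D80 (19, highest other 25), and 5 of 10 between ages in transgenic mice (23, highest other 32). It was as large in 2 of 10 in wild-type mice (27, highest other 32) and 70 of 100 for the interaction (18, highest other 31). The splits are too few for the first 4, chance is not excluded for the last, and the gene lists rest on their gene counts.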

How the results depend on the processing

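Sex as a covariate, recovered counts, leaving out Rn45s and leaving out 2 libraries were alternatives chosen after seeing the data. No named result changed its direction past the threshold in any setting. Named results called in the main setting kept their call and direction in every setting in 17 of 33 cases at D60, 100 of 128 at D80, 37 of 41 between ages in transgenic mice and 5 of 27 for the interaction. With counts recovered from the normalized table and without Rn45s, all 290 named results kept their side of the threshold. With sex as a covariate, whose effect rests on D80 transgenic replicate 1, 44 lost their call. No alternative from the plan was left out. Depth limits the scarce lymphocyte transcripts, since a group with 0 counts allows up to 3, and where a fit without a library left 2 in a group, they are assumed to vary like the others. The cause of the changes below was not tested, except that glmTreat asks for a larger change.

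For transgenic against wild-type at D60 (599 genes), 365 passed with glmTreat, 969 with DESeq2, 85 with sex as a covariate and 378 to 736 when 1 library was left out. At D80 (6354) glmTreat passed 2604, and 4416 to 7079 passed when 1 library was left out. Between ages in transgenic mice (5490) glmTreat passed 1940, and 3507 to 6594 passed when 1 library was left out. Between ages in wild-type mice (0) 5 passed with only the 2 groups, 260 with DESeq2, 1 with sex as a covariate, 7 without the 2 libraries with the most duodenal or pancreatic transcripts, and 0 to 396 when 1 library was left out. For the interaction (768) 187 passed with glmTreat, 423 with limma-voom, 1421 with limma on the deposited normalized table, 1735 with DESeq2, 99 with sex as a covariate, and 193 to 2419 when 1 library was left out. The overlap (537) was 83 with sex as a covariate and 349 to 619 when 1 library was left out. Camera called 23, 19, 23, 27 and 18 lists in the 5 comparisons, 2, 0, 0, 0 and 0 with an estimated correlation, and fry called 7, 31, 30, 0 and 2. With sex as a covariate camera called 15 lists between ages in wild-type mice. When 1 library was left out it called 17 to 23, 18 to 22, 23 to 30, 22 to 32 and 15 to 23. With the replicate block 611, 5993, 5189, 0 and 635 genes passed in the 5 comparisons.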

Other observations

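The test of duodenal tissue below was chosen after the main comparisons but before its own value was seen, and the lists of the next paragraph were described only after their results were seen.

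Further gene groups differed between the genotypes at D80. Of 11 eosinophil and type 2 genes 6 were higher and 1 lower by the edgeR test (the same adjusted over the list alone, camera adjusted p = 0.20, and adjusted p = 0.70 with an estimated correlation). The count of higher genes was 4 without D80 transgenic replicate 2. The eosinophil chemokine Ccl11 rose from 8.58 ± 1.66 to 42.2 ± 21.5 CPM (SD, n = 3, log2 fold change 2.30, SE 0.45, adjusted p = 0.0021). Retnla, a secreted product of alternatively activated macrophages, fell from 6.21 ± 3.01 to 0.229 ± 0.145 CPM (log2 fold change -4.70, SE 0.71, adjusted p = 4.2e-04). Genes of the interstitial cells of Cajal, the pacemaker cells of the gut wall, moved apart, 3 higher and 3 lower of 7 (the same adjusted over the list alone, camera adjusted p = 0.35, and adjusted p = 0.77 with an estimated correlation). The lower genes were 2 without D80 transgenic replicate 3 and 0 with no composition factor. The transcription factor Etv1 (log2 fold change 2.90, SE 0.27, adjusted p = 1.3e-05) and the receptor Kit (log2 fold change 1.68, SE 0.34, adjusted p = 0.0028), which mast cells also express, were higher. The chloride channel Ano1 was lower (log2 fold change -0.77, SE 0.15, adjusted p = 0.0023), a call lost with no composition factor (adjusted p = 0.080) and with glmTreat (adjusted p = 0.17). Of 16 immediate early genes 6 were lower (the same adjusted over the list alone, camera adjusted p = 0.20, and adjusted p = 0.76 with an estimated correlation), among them Fosb (log2 fold change -2.57, SE 0.58, adjusted p = 0.0049). That count was 9 without D80 wild-type replicate 1, 4 without D80 transgenic replicate 1, 3 without D80 wild-type replicate 2 and 2 without D80 wild-type replicate 3 or D80 transgenic replicate 2 or 3. Without D80 wild-type replicate 2 or 3, 1 gene was higher, and with no composition factor 2 were lower and 2 higher.

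The third pattern weighed is that no CD8 or cytotoxic lymphocyte gene passed the edgeR test at D80, where 0 of 9 did over all genes and adjusted over the list alone. This depends on the scaling, since 1 of the 9 was higher with no composition factor. Duodenal tissue in D80 wild-type replicate 3, which held the most transcripts of both kinds, is a candidate explanation. All 18 duodenal genes had a mean of 1 CPM or more over the wild-type libraries, but that mean includes this library and so decides nothing. The duodenal list also had signal in D60 wild-type libraries, at 1624 ± 256 summed CPM, with Vil1 at 428 ± 55.2 CPM (SD). Without that library the list's median was 0.80 in place of -0.90, and 2 of the 9 genes were higher, with a lowest adjusted p of 0.0098. Both values lie between the bounds set in advance. Duodenal tissue and a difference in lymphocytes between wild-type mice cannot be told apart, since the library was the sole one with so many transcripts of either kind. Duodenal signal was not confined to it, as the list was at 3456 ± 1281 summed CPM in D80 transgenic and 1574 ± 599 in D60 transgenic libraries (SD).

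The library D80 transgenic replicate 2, with 319 CPM of Xist (this and the next Xist values without the TMM factor), also held 13 counts of Y-linked genes, 4 of Ddx3y, 6 of Kdm5d and 3 of Uty, against 0 in each of the other 7 libraries with Xist. Xist was at 276 to 468 CPM in replicates 2 and 3 of both transgenic groups and at 91.8 to 113 CPM in D60 transgenic replicate 1 and the 3 D80 wild-type libraries. The ribosomal transcript Rn45s held 0.346% to 2.64% of the counts of a library, and the 10 most abundant genes 10.3% to 22.2%.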
